A study of Homo sapiens with 4 samples.

How the data were processed

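RNA sequencing libraries were prepared from total RNA with a TruSeq RNA kit, per the labels' protocols, from MCF-7 cells transfected with a miR-23b mimic, MCF-7 control cells, MDA-MB-231 cells with a stable miR-23b sponge and MDA-MB-231 control cells, 1 library each. The labels name the MCF-7 control miR-nc, while the treatment protocol names a miR-26a mimic as the other transfection, and no label says which was used; genes with miR-26 sites were therefore examined as well. The deposited values are RPKM, reads scaled by the authors to transcript length and library size, per the file headers, with 31106 rows of RefSeq transcripts per library. The submitters' processing notes name the genome build hg19, CASAVA 1.4 and Partek, without their roles. The aligner settings, the annotation version and the way reads were divided among transcripts of a gene are not given in the sources used here, nor is strand, so overlapping and antisense genes cannot be told apart. RPKM scales each library to its own total, so a few abundant transcripts that differ between libraries shift all other values; no further scaling was applied for the main values.

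Depth is not stated and was recovered from the values. In genes with 1 row, the low RPKM values multiplied by transcript length fall on steps of 1 read, and the step gave about 14700000 reads for the mimic library, 14500000 for the MCF-7 control, 15400000 for the sponge library and 16400000 for the MDA-MB-231 control. Of values up to 10 reads, 66.3% to 68.4% came out whole within 0.1 read, against 20% by chance, so reads were not recovered for all rows and no count model was run. Estimated reads gave exact binomial 95% intervals of the log2 ratio of RPKM for named genes. For a gene with several rows they take the reads of the chosen row as counted, which is approximate. The intervals cover counting error only, not differences between cultures or libraries.

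The 31106 rows hold 18219 gene symbols, of which 6621 have more than 1 row. A gene was represented by the row with the highest mean over the 4 libraries. Ratios were computed on log2(RPKM + 0.5) for genes with a mean of at least 1 RPKM over both libraries compared. Genes at least 2-fold apart were counted per direction. With 1 library per group no p-value across genes is given, and a gene list is described by its median and the percentile of that median among 10000 random lists of equal size matched on mean expression in 20 bins. The 28 gene lists, the rule for named genes, the comparisons and most alternatives were fixed before the data were examined. Named genes are the 8 highest and 8 lowest ratios per comparison among plain gene symbols, up to 4 members per list with the largest absolute ratio, a fixed set (PAK2, LIMK2, CFL2, ARHGEF6, PIK3R3, TLN2, PLAU, ANXA2, SMAD3, GLS and the miR-23b host gene), the 10 genes with the widest opposite difference, the 5 with the widest difference the other way, and 10 markers of the cell lines. Opposite differences were ranked by the smaller of the 2 absolute log2 ratios of a gene. Where summing the rows of a gene moved its log2 ratio by over 1.5 times, or made its difference smaller by over 1.5-fold, the summed value is given beside it. Of 25 lists with a median, 6 lay outside the 2.5 to 97.5 percentile range in the mimic comparison, 11 in the sponge comparison and 13 between the cell lines.

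Seed sites were searched in the 3' UTR of the longest coding transcript of GENCODE release 29. That annotation is on another genome build than the authors' hg19, so it served for sequences, transcript lengths and GC content by gene symbol and RefSeq accession, and no coordinates were taken from it; 99.0% of 16565 coding symbols matched, and 16343 genes had a 3' UTR. Sites were the 8mer AATGTGAA, the 7mer-m8 AATGTGA, the 7mer-A1 ATGTGAA and the 6mer ATGTGA for miR-23, and TACTTGAA, TACTTGA and ACTTGAA for miR-26, with the best class per gene. Medians were set against random lists matched on expression (5 bins) and 3' UTR length (10 bins), 10000 lists per site class and 2000 for the combined classes. These lists were drawn from all genes with a 3' UTR, those with a site included. All words of 7 bases found in at least 100 genes, and those in at least 1000 genes, were ranked by the median ratio of the genes that hold them. Bootstrap intervals used 500 draws of genes.

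The additive model with cell line and miR-23b activity was fitted with limma 3.58.1 in R 4.3.3 to log2(RPKM + 0.5), with Benjamini-Hochberg adjustment over the genes tested. All other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data with 200 changed genes. At the 2-fold threshold the ratio of 2 libraries recovered 96% of simulated 4-fold and 30% of simulated 2-fold changes in the mimic comparison, with median log2 estimates of -1.78 and -0.88, so smaller than the changes put in. The additive model recovered 100% of 4-fold and 95% of 2-fold changes when these were equal in both lines, with 13.3% of its calls wrong. The simulated libraries of a line differed only by these changes and by noise with a dispersion of 0.01. The residual thus held no differences particular to 1 line, whereas the residual of the real fit is the difference between the lines. This recovery therefore does not carry over to the real fit. Of 100 random lists 3 fell outside the 95% range, and 50 of 50 lists shifted by 0.3 lay above it. Those lists were random draws of simulated genes with independent noise, so these rates do not carry over to the real lists either.

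Alternatives were scaling by the median of ratios or by the upper quartile, a pseudocount of 0.1 or 1, no filter on low values or a mean of at least 5, 8mer sites alone, the 3' UTRs of all transcripts, and limma with its trend option. For the numbers of genes at least 2-fold apart, summing the rows of a gene was planned as well. Chosen after seeing the data were the summed rows for other results, the restriction to genes with 1 row, the removal of a trend on transcript length and GC content, and the reported-target list without 8 genes. DDIT3, TGFBR2 and other genes with several rows are given for 1 transcript. Some rows of such genes hold values far below 1 read, such as 0.00047 RPKM for RABL2B in the MCF-7 control, so reads were divided among transcripts by estimation and the values of single rows depend on it.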

Results

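Messenger RNA was measured by RNA sequencing in 4 libraries from 2 human breast cancer cell lines. MCF-7 is an estrogen receptor-positive line of epithelial character, and MDA-MB-231 is an estrogen receptor-negative line of mesenchymal-like character. miR-23b is a microRNA, a short RNA that pairs through its seed with matching sites in the 3' untranslated region (3' UTR) of mRNAs and lowers their level or translation. In MCF-7 cells miR-23b was raised by transient transfection of a mimic, a synthetic copy of the microRNA, and the library was set against a control library labelled miR-nc. In MDA-MB-231 cells its activity was lowered by a stably transfected sponge vector, whose transcript carries binding sites that occupy the microRNA, and the library was set against a control whose column header names pEGFP, a plasmid for green fluorescent protein. The series asks which genes respond to miR-23b, with cytoskeletal remodelling as its background. The microRNA itself has no row in the tables. Its host gene C9orf3 stood at 2.15 RPKM (reads scaled to transcript length and library size) in the mimic library, 4.60 in the MCF-7 control, 4.92 in the sponge library and 5.05 in the MDA-MB-231 control; with its rows summed it was lower with the mimic (log2 ratio -0.91) and stood at 0.47 with the sponge.

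Each group held 1 library. No difference below therefore has a replicate check, and each is a difference between libraries that cannot be separated from chance differences between cultures. The depth recovered from the steps of the low values was about 14700000 reads for the mimic library, 14500000 for the MCF-7 control, 15400000 for the sponge library and 16400000 for the MDA-MB-231 control. Between 10513 and 10807 genes reached 1 RPKM in a library, and the 10 most abundant transcripts took 4.92% to 7.26% of the RPKM total. Ratios are log2 ratios of RPKM + 0.5, which understates differences of low genes. Intervals are 95% counting intervals of the log2 ratio of RPKM without the pseudocount, and they cover counting error only.

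The control libraries carried the markers of their lines. ESR1, the estrogen receptor, was listed at 22.9 RPKM in the MCF-7 control and was close to 0 in the MDA-MB-231 control. The luminal transcription factor GATA3 stood at 194 against 0.94 RPKM, keratin KRT8 at 1049 against 38.4, the adherens junction cadherin CDH1 at 233 against 0.04 and EPCAM at 61.4 against 3.22. The mesenchymal filament gene VIM was higher in the MDA-MB-231 control, at 1332 against 2.61 RPKM, as were the receptor kinase AXL (79.8 against 0.02), the adhesion receptor CD44 (94.2 against 0.11; log2 ratio 7.28, or 3.24 with its rows summed) and the repressor ZEB1 (7.52 against 0.01). The caveolar gene CAV1 differed little, at 32.2 RPKM in the MDA-MB-231 control and 43.0 in the MCF-7 control (log2 ratio -0.41, or -0.13 with its rows summed). Of 11330 genes with a mean of at least 1 RPKM, 2408 were at least 2-fold higher and 2207 at least 2-fold lower in the MDA-MB-231 control, and the correlation of the log values across genes was 0.55. The 18 measured MDA-MB-231 markers had a median log2 ratio of 5.93 and the 19 MCF-7 markers one of -4.56. Epithelial junction and keratin genes had a median of -3.26 (37 genes), estrogen-response genes -3.80 (30 genes), mesenchymal genes 3.99 (19 genes) and genes of extracellular proteolysis 3.15 (20 genes). Each of these 6 medians lay outside the 95% range of 10000 random lists matched on expression.

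The first comparison asks which mRNAs were lower after the miR-23b mimic. In the mimic library, mRNAs with a miR-23 seed site in the 3' UTR were lower than those without one, and the difference grew with the strength of the site. The 1030 genes with an 8mer site (AATGTGAA) had a median log2 ratio of -0.074, the 1098 genes with a 7mer-m8 site (AATGTGA) one of -0.041 and the 904 genes with a 7mer-A1 site (ATGTGAA) one of -0.018, against 0.030 in 5892 genes without even a 6mer. Of the 8mer genes 10.1% were at least 1.5-fold lower, against 6.11% of the genes without a 6mer. None of 10000 random lists matched on expression and 3' UTR length had a median as low as the 8mer genes, whose matched range was -0.028 to 0.013. The 7mer-m8 median lay at the 0.06 percentile of its matched lists and the 7mer-A1 median at the 11.4 percentile, inside the range. The shift was small: 3032 genes with any 7mer or 8mer differed from genes without a 6mer by -0.072 (bootstrap 95% interval over genes -0.091 to -0.052), and by -0.036 with no filter on low values. Genes without a 6mer have shorter 3' UTRs, with a median of 766.5 against 2800.5 bases. The 3032 genes had a median of -0.043, against -0.0076 in lists matched on expression and 3' UTR length. The matched lists were drawn from all genes, those with a site included. What part of the -0.072 goes with 3' UTR length or expression therefore cannot be read from them. Genes with a 6mer alone, with a median 3' UTR of 2168 bases, had a median of 0.022, which differed from genes without a 6mer by -0.0075. Genes with a 7mer or 8mer site for miR-26, the other mimic named in the treatment protocol, had a median of -0.006 and lay at the 64.6 percentile of matched lists. They differed from genes without a miR-26 6mer by -0.019 (bootstrap interval over genes -0.034 to -0.0036).

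**Figure D1:**
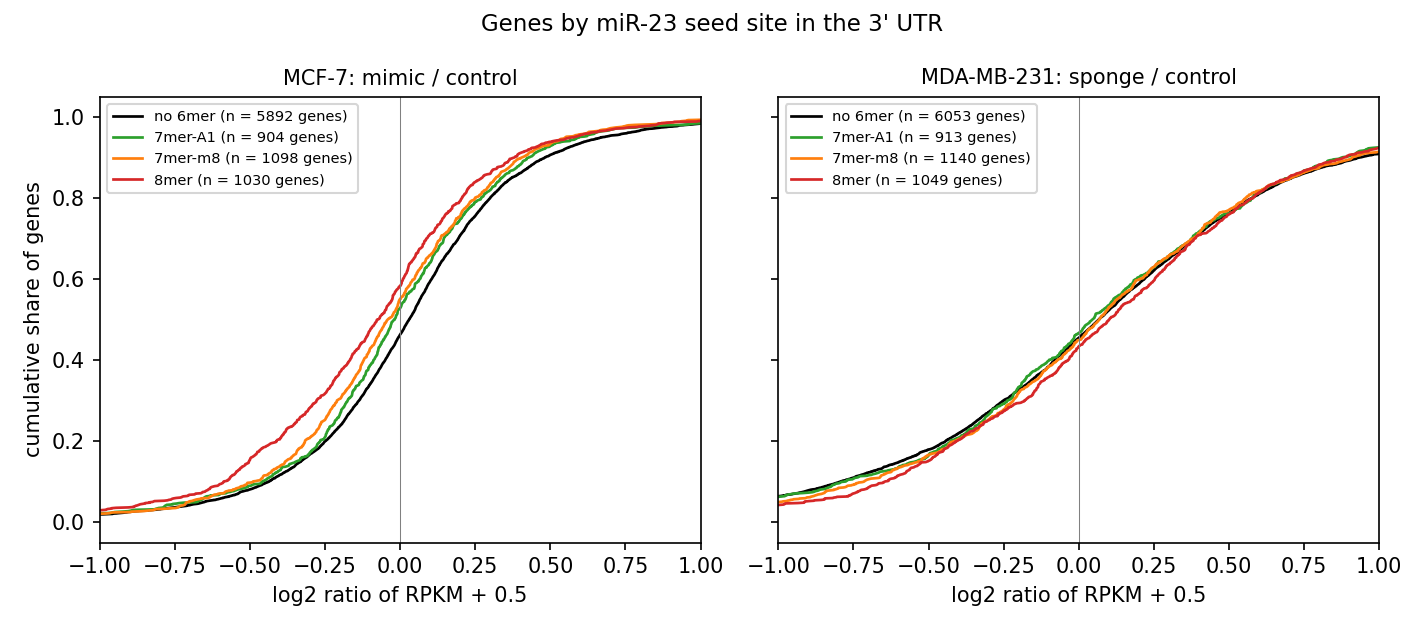
Cumulative share of genes (y axis) by log2 ratio of RPKM + 0.5 (x axis), for genes without a miR-23 6mer in the 3' UTR and for genes whose best site is a 7mer-A1, 7mer-m8 or 8mer. The 8mer curve lies left of the curve without a 6mer in the mimic comparison (medians -0.074 and 0.030), while the curves nearly coincide in the sponge comparison. The curves are not matched on 3' UTR length, which in the mimic comparison has a median of 2898 bases for 8mer genes and 766.5 without a 6mer.

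Genes reported in the literature as miR-23a or miR-23b targets were lower in the mimic library as a group. Of 35 measured members 9 were at least 1.5-fold lower and 1 was higher, and the median of -0.22 lay at the 0.03 percentile of matched random lists. Among 44 list members with a 3' UTR, 43 hold a 7mer or 8mer site. The list is not fully independent of these libraries, since 8 of its genes may have been chosen from them. These are PAK2, LIMK2, CFL2, ARHGEF6, PIK3R3, TLN2, PLAU and ANXA2. Without those, 30 genes had a median of -0.17 at the 0.4 percentile. Of those 30, 5 were at least 1.5-fold lower and 1 was higher. PAK2, a kinase that acts downstream of RAC1 and CDC42 on the actin cytoskeleton, stood at 24.8 against 39.5 RPKM, 1.58-fold lower (log2 ratio -0.66, interval -0.75 to -0.59). PIK3R3, a regulatory subunit of phosphoinositide 3-kinase, stood at 7.97 against 16.4 RPKM (-0.99, interval -1.18 to -0.90), and ANXA2, a calcium-dependent membrane and actin-binding protein, at 39.2 against 62.8 RPKM (-0.67). TGFBR2, a TGF-beta receptor, stood at -1.60 (-0.84 with its transcript rows summed), the chemokine CXCL12 at -1.18, and CFL2, which severs actin filaments, at -1.08 (-0.20 with the rows summed). GLS, the glutaminase, stood at -0.22, LIMK2, a kinase of cofilin, at -0.08 (-0.46 with the rows summed) and SMAD3, a signal transducer of TGF-beta, higher at 10.4 against 5.28 RPKM (0.92). PAK2, PIK3R3, TGFBR2, CXCL12 and CFL2 carry an 8mer site, GLS, LIMK2 and SMAD3 a 7mer-m8 site and ANXA2 a 7mer-A1 site. ARHGEF6, TLN2 and PLAU were under the filter in MCF-7.

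Cytoskeletal genes showed no common direction in the mimic library. Of 69 actin regulators 5 were at least 1.5-fold higher and 5 lower, with a median of 0.003 that changes sign with the scaling (28.1 percentile). EVL, which promotes filament elongation, was lower at 15.0 against 41.1 RPKM (-1.43), and RDX, which links actin to the membrane, was higher at 66.2 against 33.7 (0.96). Of 35 focal adhesion and integrin genes 4 were higher and 4 lower (median 0.04, 69.1 percentile), with CAV1 lower at 12.6 against 43.0 RPKM (-1.73, and -1.91 with the rows summed). The list median was 0.30 among genes with 1 row and -0.008 with the rows summed. The kinase SRC was higher in its chosen row (0.99) but not with the rows summed (-0.11), and the integrin ITGA6 stood at 0.94, or 0.38 summed. Of 24 microtubule genes 4 were lower and 0 higher (median -0.015, 28.8 percentile), among them MAPRE2 at -1.998 (-1.17 summed), MARK2 at -1.02 (-0.14 summed) and the tubulin TUBA1A at -0.83. Epithelial junction and keratin genes (36 measured, median -0.014) and TGF-beta pathway genes (25 measured, median 0.004) lay inside their matched ranges as well. Of 9 mesenchymal genes 4 were higher and 2 lower, with a median of 0.15 that turned to -0.022 with no filter and to -0.21 among genes with 1 row. TGFBI, an extracellular matrix protein, stood at 12.4 against 3.26 RPKM (1.78), the collagen COL3A1 at 2.24 against 7.47 (-1.54) and VIM at 0.79 against 2.61 (-1.26).

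Interferon-response genes were lower in the mimic library than in its control. Of 23 measured members 15 were at least 1.5-fold lower and 0 higher, and none of 10000 matched lists had a median as low as -0.94. IFI6 stood at 0.22 against 14.6 RPKM (-4.40, or -3.41 with its rows summed), IFIT1, which binds foreign RNA ends, at 0.73 against 7.62 (-2.72), IFI27 at 0.30 against 3.30 (-2.24) and IRF9, a subunit of the interferon-activated factor, at 2.59 against 8.86 (-1.60). Histone genes were also lower, with 5 of 9 at least 1.5-fold lower, 0 higher and a median of -0.73 that no matched list reached; HIST1H4H stood at 3.085 against 11.04 RPKM and HIST2H2BE at 25.9 against 70.5. The multicopy histone genes share near-identical sequence, so single members are uncertain.

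AP-1 and immediate early genes were higher in the mimic library, with 8 of 24 at least 1.5-fold higher, 0 lower and a median of 0.35 above that of all 10000 matched lists. FOSL1 stood at 6.31 against 2.23 RPKM (1.32), EGR1 at 118 against 49.1 (1.26, interval 1.19 to 1.34) and the phosphatase DUSP4, a feedback inhibitor of MAP kinases, at 31.1 against 13.1 (1.22). Cell cycle genes lay slightly higher, with a median of 0.26 over 42 genes that exceeded all matched lists, 4 of them at least 1.5-fold higher and 0 lower. Among these, the mitotic kinesin KIF20A stood at 24.0 against 14.4 RPKM (0.71) and cyclin CCNA2 at 27.1 against 17.6 (0.60). Estrogen-response genes had a median of 0.13 over 29 genes (0.27 among genes with 1 row), just inside the matched range (97.3 percentile). Their members parted: TFF1, a classical estrogen target, was higher at 742 against 334 RPKM (1.15) and the growth factor AREG at 140 against 52.5 (1.402), while the progesterone receptor PGR was lower at 3.88 against 11.7 (-1.47).

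The remaining lists in the mimic comparison stayed inside their matched ranges, except for the MDA-MB-231 markers. Only 5 of those markers were measured in MCF-7, and their median of -0.81 (0.065 percentile) turned to 1.32 when only genes with 1 transcript row were used. NF-kB and inflammatory genes had a median of 0.27 over 8 genes (-0.019 with no filter on low values), p53 and apoptosis genes -0.14 over 27 (-0.30 among genes with 1 row), glutamine metabolism 0.13 over 18 (0.055 with no filter), oxidative phosphorylation 0.10 over 44, extracellular proteolysis 0.11 over 10 (0.034 among genes with 1 row) and hypoxia and glycolysis 0.07 over 20. Unfolded protein and stress response genes had a median of -0.019 over 22 (-0.27 among genes with 1 row, -0.15 with no filter). Among them the heme oxygenase HMOX1 was far below its control at 4.74 against 27.1 RPKM (-2.40). Cholesterol synthesis (-0.029, 23 genes), microRNA machinery (-0.032, 13 genes), ribosomal proteins (0.006, 65 genes), reference genes (-0.006, 15 genes) and MCF-7 markers (-0.034, 19 genes) were near 0. None of the leukocyte markers passed the filter, and 2 fibroblast or endothelial markers did, the collagens COL3A1 and COL1A1 (0.15).

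Of 10637 genes compared in MCF-7, 160 were at least 2-fold higher and 218 at least 2-fold lower in the mimic library, and the log values correlated at 0.961 across genes. The largest ratios above the control were those of FANCL (2.92), CYB5A (2.81), INSL4 (2.72), RABL2B (2.37 against 0.00047 RPKM, 2.52), TGM2 (2.28), FAM203A (2.03), GAL (2.02) and SUSD3 (2.01). The protein-crosslinking enzyme TGM2 stood at 11.03 against 1.88 RPKM (interval 2.29 to 2.82), and the neuropeptide GAL at 6.54 against 1.24. With their transcript rows summed FANCL came to 0.04, CYB5A to 0.18, RABL2B to 0.38 and FAM203A to -0.24, so that the ratios of these 4 are those of single annotated transcripts. RABL2B and FAM203A also have near-identical copies. The lowest ratios belonged to IFI6 (-4.40), the potassium channel gene KCNJ8 (1.03 against 15.5 RPKM, -3.39), the cadherin CDH18 (0.45 against 9.34, -3.37), MDP1 (-3.02), ARHGAP36 (1.91 against 16.9, -2.85), IFIT1 (-2.72), FAM104B (-2.47) and BNIPL (-2.44). With their rows summed IFI6 came to -3.41, MDP1 to -0.06, FAM104B to 0.05 and BNIPL to -1.64. Sites stood on both sides. Among the 8 highest TGM2 carries an 8mer and INSL4 a 7mer-A1 site. Among the 8 lowest IFIT1 carries an 8mer and IFI6 a 7mer-A1 site. The count of 2-fold genes depended on low values: 56 were higher and 68 lower among genes with a mean of at least 5 RPKM.

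The second comparison asks which mRNAs were higher where miR-23b was sequestered. Cell cycle, cholesterol synthesis and microtubule genes were higher in the sponge library, and stress-response genes were lower. The differences were wider than in MCF-7: of 10923 genes 946 were at least 2-fold higher and 664 at least 2-fold lower, 14.7% of genes against 3.55% with the mimic, and the log values correlated at 0.875. The split depends on scaling, since scaling by the upper quartile shifted the median of all genes by -0.12 and gave 732 genes higher and 837 lower. List percentiles compare genes within the same pair of libraries.

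Of 41 cell cycle genes 30 were at least 1.5-fold higher and 1 lower, with a median of 1.55 above all 10000 matched lists. KIF20A stood at 50.4 against 2.72 RPKM (3.98, interval 3.97 to 4.47), the mitotic kinase PLK1 at 31.6 against 2.72 (3.32), CDC20, an activator of the anaphase-promoting complex, at 56.8 against 5.27 (3.31) and cyclin CCNB1 at 86.0 against 10.6 (2.96). Cholesterol synthesis genes were higher in 19 of 24 cases and lower in 1, with a median of 1.53 above all matched lists. DHCR24, which catalyses a late step of the pathway, stood at 95.6 against 10.3 RPKM (3.15), PCSK9, which directs the LDL receptor to degradation, at 26.4 against 3.43 (2.78) and mevalonate kinase MVK at 9.31 against 1.79 (2.10).

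Unfolded protein and stress response genes were lower in the sponge library in 20 of 24 cases and higher in 1, with a median of -1.76 below all matched lists. The chaperone HSPA5 stood at 169 against 1123 RPKM (-2.73, interval -2.76 to -2.70), the pseudokinase TRIB3 at 3.82 against 53.3 (-3.64), asparagine synthetase ASNS at 6.45 against 52.0 (-2.92) and the stress transcription factor DDIT3 at 0.34 against 40.5 (-5.61, and -2.61 with its rows summed). Glutamine metabolism genes shared this direction, with 10 of 19 lower, 2 higher and a median of -0.65 (-0.41 with no filter on low values); ASNS belongs to both lists, and the serine synthesis enzymes PHGDH (4.94 against 26.4 RPKM, -2.31) and PSAT1 (13.7 against 42.4, -1.60) were among the lowest. GLS, the glutaminase, went the other way at 6.30 against 4.15 RPKM (0.55). NF-kB and inflammatory genes were lower in 11 of 21 cases and higher in 3 (median -0.64, and -0.31 among genes with a mean of at least 5 RPKM), with the adhesion molecule ICAM1 at 5.99 against 46.3 RPKM (-2.85) and RELB at 1.34 against 8.24 (-2.25), while the cytokine IL11 was higher at 37.9 against 8.97 (2.02). Ribosomal protein genes were lower, with a median of -0.37 over 65 genes, 13 of them at least 1.5-fold lower and 1 higher. No matched list had a median as low as those of the glutamine, NF-kB and ribosomal lists.

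Microtubule genes and actin regulators were higher in the sponge library. Of 23 microtubule genes 14 were at least 1.5-fold higher and 0 lower, and the median of 0.72 (1.46 among genes with 1 row) lay above all matched lists. The tubulins TUBA1A (96.7 against 17.7 RPKM, 2.42), TUBA1B (751 against 178, 2.08), TUBB2A (23.1 against 5.70, 1.93) and TUBA1C (438 against 121, 1.86) led the list, and these copies share sequence, so their division of reads is uncertain. Of 73 actin regulators 27 were higher and 5 lower, with a median of 0.35 (0.21 when scaled by the upper quartile) at the 99.55 percentile. TAGLN, an actin-bundling protein, stood at 6.30 against 0.59 RPKM (2.64), the myosin light chain MYL9 at 101 against 15.9 (2.62), CNN3 at 157 against 42.0 (1.89) and the tropomyosin TPM1 at 20.6 against 5.22 (1.88). Of 36 focal adhesion and integrin genes 9 were higher and 5 lower (median 0.18, 73.2 percentile). This median was 0.091 when scaled by the median of ratios, 0.043 by the upper quartile and 0.081 at a mean of at least 5 RPKM. The scaffold NEDD9 was higher at 6.42 against 1.02 RPKM (2.19) and the collagen receptor ITGA2 lower at 21.7 against 74.2 (-1.75). Of 20 mesenchymal genes 10 were higher and 3 lower, with a median of 0.58 (0.24 among genes with a mean of at least 5 RPKM, 1.04 among genes with 1 row) at the 99.7 percentile; the repressor SNAI2 stood at 24.7 against 3.26 RPKM (2.74) and the collagen-crosslinking enzyme LOX at 8.93 against 32.4 (-1.80). Genes of extracellular proteolysis had a median of -0.21 over 20 genes at the 2.11 percentile (-0.067 with no filter on low values or among genes with 1 row, and -0.34 when scaled by the upper quartile), 7 lower and 3 higher, and parted: the collagenase MMP1 stood at 7.18 against 761 RPKM (-6.63) and the plasminogen activator PLAU at 64.6 against 20.8 (1.61).

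Interferon-response genes were higher in the sponge library, with 13 of 28 at least 1.5-fold higher, 4 lower and a median of 0.47 (0.74 among genes with a mean of at least 5 RPKM) at the 99.85 percentile. OASL stood at 9.73 against 0.27 RPKM (3.74), IFIT1 at 28.7 against 4.35 (2.59), IFIT2 at 30.9 against 5.12 (2.48) and IFIT3 at 36.0 against 6.92 (2.30, or 1.62 with its rows summed). The immediate early genes FOS (1.18 against 11.8 RPKM, -2.88) and EGR1 (5.10 against 28.6, -2.38) were lower, while their list of 21 held 7 members higher and 5 lower (median -0.18, 3.02 percentile), and the median turned to 0.022 at a mean of at least 5 RPKM and to 0.23 among genes with 1 row. Oxidative phosphorylation genes had a median of 0.34 over 44 (0.21 when scaled by the upper quartile, 96.2 percentile), with 11 higher and 0 lower. Reference genes, meant to be stable, had a median of 0.27 over 15 (0.13 when scaled by the upper quartile) with 4 higher and 1 lower, inside the matched range; ACTB stood at 1216 against 470 RPKM (1.37) and EEF1A1 at 999 against 2990 (-1.58). Medians inside the matched ranges were also found for epithelial junction and keratin genes (0.03, 22 genes), TGF-beta pathway genes (-0.11, 27 genes), estrogen-response genes (0.006, 15 genes), p53 and apoptosis genes (0.15, 27 genes), hypoxia and glycolysis genes (0.04, 23 genes), microRNA machinery (0.24, 15 genes), histone genes (-0.22, 8 genes), MCF-7 markers (0.02, 10 genes) and MDA-MB-231 markers (-0.024, 19 genes). Of these, the medians of the epithelial, estrogen-response, hypoxia and MCF-7 marker lists changed sign with the scaling. That of the MDA-MB-231 markers turned to 0.075 with no filter on low values and to 0.22 among genes with 1 row. Scaled by the upper quartile the median was 0.021 for p53 and apoptosis, -0.24 for the TGF-beta pathway, 0.12 for microRNA machinery and -0.33 for histone genes. The microRNA machinery came to 0.015 at a mean of at least 5 RPKM. Histone genes came to -0.36 with the rows summed and to -0.02 with no filter on low values. A single leukocyte marker passed the filter, CD68, at 38.9 against 93.3 RPKM (-1.25), and 2 fibroblast or endothelial markers did, KDR (-1.05) and COL1A1 (0.80).

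**Figure D2:**
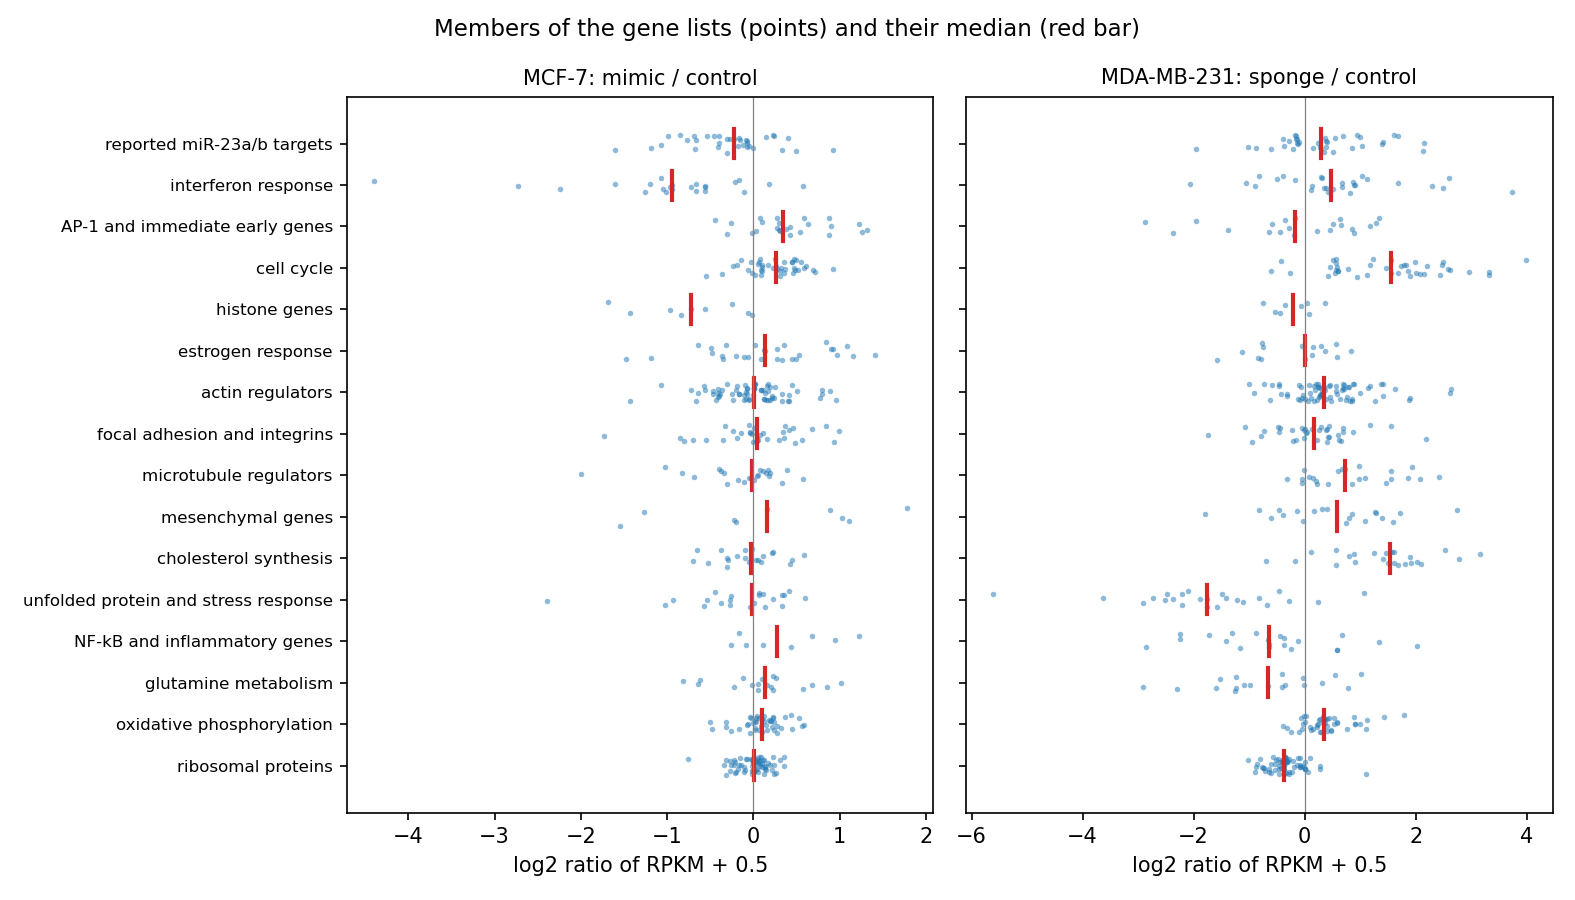
Log2 ratio of RPKM + 0.5 (x axis) of each measured member (points) of 16 gene lists and the list median (red bar), for the mimic library against the MCF-7 control (left) and the sponge library against the MDA-MB-231 control (right). Interferon genes have a median of -0.94 on the left and 0.47 on the right, and the sponge panel spreads more widely, with medians of 1.55 for cell cycle and -1.76 for stress-response genes.

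Reported miR-23 targets were higher in the sponge library in 11 of 37 cases and lower in 4, with a median of 0.29 (0.18 when scaled by the upper quartile) at the 95.0 percentile of matched lists, inside the 95% range. Without the 8 genes that may have been chosen from these libraries the median was 0.26 over 30 genes, at the 90.6 percentile. Of those 30, 7 were higher and 4 lower. PAK2 stood at 39.0 against 19.4 RPKM (0.99, interval 0.93 to 1.09), ANXA2 at 178 against 86.8 (1.03), PLAU at 64.6 against 20.8 (1.61) and PIK3R3 at 3.35 against 0.38 (2.13, or 1.51 with its rows summed). The mitotic kinase NEK2 (15.6 against 3.16 RPKM, 2.14) and lamin LMNB1 (27.2 against 8.17, 1.68) were higher and the coactivator PPARGC1A lower (0.53 against 3.50, -1.96). NEK2 is the list member without a 7mer or 8mer site and holds a 6mer alone, while LMNB1 holds a 7mer-A1 and PPARGC1A an 8mer site. TLN2 stood at 0.38, LIMK2 at -0.12 (0.10 with the rows summed), SMAD3 at -0.13 (-0.26 with the rows summed) and CFL2 at -0.11 (0.19 with the rows summed), and ARHGEF6 was under the filter at 0.85 against 0.21 RPKM. Across the transcriptome the site classes differed little. The 1049 genes with an 8mer site had a median of 0.10, above the matched range of 0.019 to 0.097 (98.6 percentile), while the 7mer-m8 genes (0.069) and the 7mer-A1 genes (0.046) lay inside theirs. All 3102 genes with a 7mer or 8mer site had a median of 0.072 against 0.067 in 6053 genes without a 6mer, at the 93.25 percentile, and the difference of 0.005 had a bootstrap interval over genes of -0.027 to 0.037.

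The highest ratios in the sponge library belonged to SPANXB1 (77.5 RPKM), SPANXA2 (17.9 RPKM) and COX7B2 (13.4 RPKM), each listed at 0 in the control, followed by KIF20A (3.98), OASL (3.74), CDCA3 (3.69), CPA4 (3.67) and FAM58A (3.65, or 1.39 with the rows summed). The SPANX genes are near-identical copies, so reads cannot be assigned to one of them with certainty. The lowest belonged to MMP1 (-6.63, interval -6.93 to -6.54), DDIT3 (-5.61), SERPINB2 (0.07 against 22.3 RPKM, -5.33), BEX2 (0.01 against 15.7, -4.98, or -3.81 with the rows summed), the stress-induced cytokine GDF15 (1.301 against 39.6, -4.48), the heat shock gene HSPA6 (-4.20), SLFN5 (1.06 against 22.1, -3.86) and TRIB3 (-3.64).

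The third comparison asks which genes were lower with more miR-23b activity in MCF-7 and higher with less of it in MDA-MB-231. Among 9496 genes measured in both lines, 132 were at least 1.5-fold lower with the mimic and at least 1.5-fold higher with the sponge, against 100 expected of independent lists. The excess was not confined to that direction, since the ratio of observed to expected was 1.32 there, 1.48 for genes higher with the mimic and lower with the sponge (103 genes), 1.27 for genes lower in both (87) and 1.21 for genes higher in both (123). The log2 ratios of both comparisons were nearly uncorrelated across genes, with Pearson's r of 0.032 and Spearman's rho of 0.050; genes are not independent replicates. Of the 124 genes in the first class with a 3' UTR, 44 (35.5%) held a 7mer or 8mer miR-23 site, against 28.2% in matched draws, at the 97.8 percentile. Genes lower in both lines held a site nearly as often (35.4%, 90.3 percentile), genes higher in both less often than matched draws (17.2%, 1.83 percentile), and genes higher with the mimic and lower with the sponge in 26.5% of cases (44.5 percentile).

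Opposite differences were ranked by the smaller of the 2 absolute log2 ratios of a gene, so a gene with 1 modest ratio ranks low. By this rule the widest, lower with the mimic and higher with the sponge, were those of IFIT1 (-2.72 and 2.59), SPANXA2 (-2.25 with the mimic, and 17.9 RPKM with the sponge against 0 in its control), the chloride channel family member CLIC3 (-1.59 and 2.05), CAV1 (-1.73 and 1.55), FILIP1L (-1.999 and 1.49), SNX16 (-1.48 and 1.57), TM2D2 (-1.48 and 1.33), KITLG, the ligand of the KIT receptor (-1.32 and 1.41), the collagen COL12A1 (-2.14 and 1.29) and the interferon-induced HERC6 (-1.25 and 1.68). With the rows summed SNX16 came to -0.14 and 0.73, TM2D2 to -0.48 and 0.35 and HERC6 to -0.82 and 0.98. Of these 10 genes IFIT1 carries an 8mer site and TM2D2 and KITLG a 7mer-m8 site. PAK2 (-0.66 and 0.99), ANXA2 (-0.67 and 1.03) and PIK3R3 (-0.99 and 2.13) took opposite directions as well. They are among the 8 targets that may have been chosen from these libraries, so their directions are no independent support. Of the same 8, CFL2 (-1.08 and -0.11) and LIMK2 (-0.08 and -0.12) were lower in both. With the rows summed these came to -0.20 and 0.19 for CFL2 and to -0.46 and 0.10 for LIMK2. By the same rule the widest differences the other way, higher with the mimic and lower with the sponge, were those of RABL2B (2.52 and -1.53, or 0.38 and -0.84 with the rows summed), MUC5B (1.48 and -3.02), B3GNT3 (1.48 and -1.83), GDF15 (1.27 and -4.48) and EGR1 (1.26 and -2.38). Of these 5, EGR1 carries a 7mer-A1 site.

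**Figure D3:**
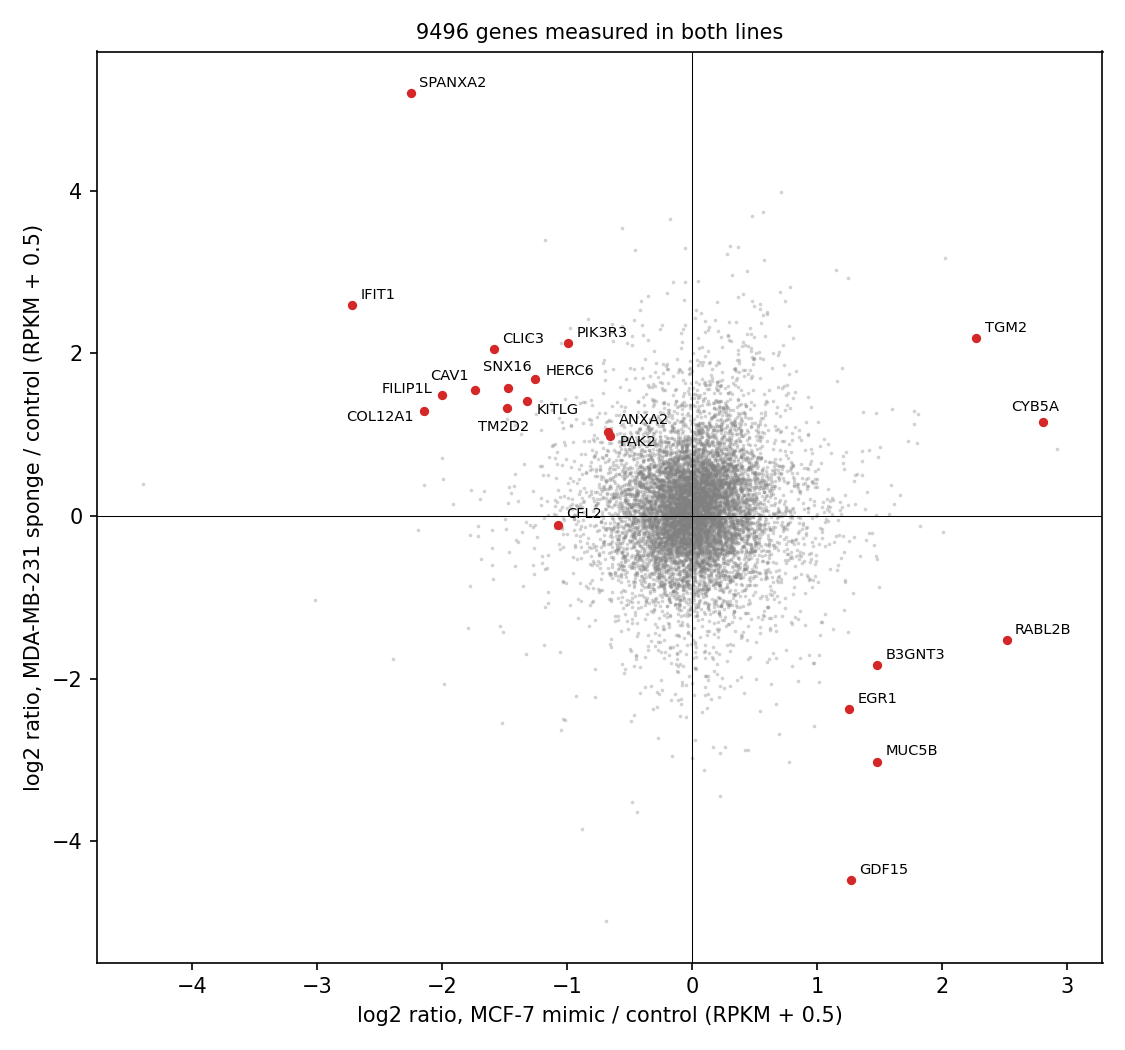
Log2 ratio of RPKM + 0.5 in MCF-7 (mimic over control, x axis) against MDA-MB-231 (sponge over control, y axis) for 9496 genes, 1 point per gene, with named genes in red. IFIT1, CAV1 and PAK2 lie in the upper left quadrant, EGR1 and GDF15 in the lower right, and the cloud as a whole has a correlation of 0.032. PAK2, PIK3R3, ANXA2 and CFL2 are targets that may have been chosen from these libraries.

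An additive model of cell line and miR-23b activity (high in the mimic library and the MDA-MB-231 control, low in the other 2 libraries), fitted with limma to 11322 genes on 1 residual degree of freedom, found 0 genes at a Benjamini-Hochberg adjusted p under 0.05. IFIT1 ranked first, lower at high activity by a log2 ratio of -2.66 (SE 0.31, limma p 0.00011, adjusted p 0.999). At an unadjusted p under 0.05 the model gave 385 genes, 162 higher and 223 lower at high activity. Uniform p-values would give 566, but the residual holds differences between the lines, so 566 is not a firm chance count. With limma's trend option the counts were 0 and 391. The residual of this fit is the difference between the lines, so the fit tests only an effect of equal size in both. The log2 ratios spread more with the sponge (SD 0.77) than with the mimic (SD 0.43), which enlarges this residual. Finding 0 genes therefore does not exclude effects shared by the lines.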

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

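Chosen only after the data were seen were the test on mixed MCF-7 cells, the tests with the trend on length and GC content removed, the word ranks among words in at least 1000 genes and the summed rows. The sign of miR-23b activity was turned in opposite ways in the 2 lines, so a response to it would give opposite ratios. The cell cycle list went the same way in both, with a median log2 ratio of 0.26 in the mimic library and 1.55 in the sponge library, as did TGM2 (2.28 and 2.19), CYB5A (2.81 and 1.16), FAM203A (2.03 and 3.17) and, downward, MDP1 (-3.02 and -1.03). Set against the intended change of activity, these ratios have opposite signs in the 2 lines. Whether miR-23b caused them was not tested, nor was the difference between the lines, since each group holds 1 library. The mimic ratios of CYB5A, FAM203A and MDP1 belong to single transcript rows and came to 0.18, -0.24 and -0.06 with the rows summed.

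Genes with a miR-23 seed site were lower in the mimic library, and in the sponge library only the 8mer class stood above its matched lists (98.6 percentile). Long 3' UTRs rather than the seed site are argued against as the whole cause for the mimic, since the median of genes with a 7mer or 8mer site lay at percentile 0 among 2000 lists matched on 3' UTR length. So is the base composition of the site rather than its order, since AATGTGA ranked 1 of 210 among words of the same bases, and 1 of 7734 among words found in at least 1000 genes (64 of 15589 among words in at least 100 genes, where small sets scatter more). A miR-26a mimic in the MCF-7 control library would place genes with miR-26 sites above their matched lists, and they lay at the 64.6 percentile. A response of mRNAs to the miR-23b mimic is a hypothesis that stays, found and tested on the same 2 libraries. An effect of the control transfection and a difference between single cultures stay open too, untested. In the sponge library genes with any 7mer or 8mer site stayed inside the lists matched on 3' UTR length (93.25 percentile). Those lists hold genes with a site, which draws the percentile toward the middle. AATGTGA ranked 29 of 210 from the top among words of the same bases. Among words in at least 1000 genes it ranked 586 of 7987 (376 with the trend on 3' UTR length removed). The site did not stand apart there as it did with the mimic, and the displacement of its 8mer class stays open.

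Interferon genes were lower in the mimic library. Sites in the genes themselves are argued against as the whole cause, since the 14 of 23 members without a 7mer or 8mer site had a median of -0.99 (-0.56 for the 9 members with one), below all matched lists. A trend on transcript length or GC content is argued against too, since 97.49% of the median remained with the trend removed. What stays open, untested, is an indirect response to miR-23b, a response of the MCF-7 control culture to its own transfection, and a difference between single cultures.

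In the sponge library cell cycle and cholesterol genes were higher and stress-response genes lower. A length or GC content trend is argued against, since at least 97.7% of each of the 3 medians remained with the trend removed, and so are miR-23 sites in the cell cycle and cholesterol genes, since the 48 of 65 members without a site had a median of 1.56 (1.501 with a site). MCF-7 cells mixed into the sponge culture are argued against, since 12 abundant MCF-7 markers reached a median of 2.41% of their MCF-7 level. KRT19 (25.01%), CLDN4 (15.2%) and KRT18 (14.8%) stood highest and above the MDA-MB-231 control (89.8 against 50.7 RPKM for KRT19), while FOXA1 and CDH1 stood at 0.02% and TFF1 at 0.12%, and cells of another line would bring all of their abundant transcripts. Growth state, nutrient stress in the control culture, clonal differences of a stable line and the sponge itself stay open; none of them was tested, because the design gives 1 culture of each.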

How the results depend on the processing

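Chosen after seeing the data were the values for genes with 1 row, for the trend on length and GC content removed, and for summed rows other than in the 2-fold counts. Across the 12 results that answer a comparison, 87 of 110 alternative values stayed within 1.5 times of a count or within the bootstrap interval of a median, and 23 moved. Of the 87, 2 changed sign near 0, the sponge seed-site difference (0.005) at -0.0057 with 1 row and -0.0012 with the trend removed. The number at least 2-fold higher with the mimic (160) was 255 with a pseudocount of 0.1, 103 with a pseudocount of 1, 56 at a mean of at least 5 RPKM and 68 among genes with 1 row; the number lower (218) was 143 with a pseudocount of 1, 332 with no filter, 68 at a mean of at least 5 and 105 with 1 row. At a mean of at least 5 and with 1 row the sponge counts were 574 and 496 higher and 330 and 378 lower, and those of the cell lines 1272 and 1385 higher and 1264 and 1352 lower. Both settings test fewer genes. Genes lower with the mimic and higher with the sponge (132) numbered 202 with no filter, 39 at a mean of at least 5 and 59 with 1 row. The seed-site difference with the mimic (-0.072) was -0.036 with no filter and -0.10 for 8mer sites alone, the correlation of both comparisons 0.073 at a mean of at least 5, and the miR-26 difference 0.0082 with the trend removed; the cause was not tested. The additive limma model found 0 genes in each of the 7 alternatives run, with 193 to 523 at an unadjusted p under 0.05.

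Of the alternative list medians, 438 of 448 stayed within the bootstrap interval, and 32 of these 438 changed sign. Some intervals are wide, so lying inside them says little about stability. With the mimic they ran from -1.26 to 1.03 for mesenchymal genes and from -1.73 to 1.78 for MDA-MB-231 markers. Signs changed in 34 of the 448, from 16 medians, of which 1 lay outside its matched range, the MDA-MB-231 markers with the mimic, at 1.32 with 1 row, where fewer members are left. Of the named genes 8 changed sign with the rows summed: C9orf3, CFL2 and LIMK2 with the sponge, under 1.5-fold apart in the chosen row, and FAM104B (from -2.47 to 0.048), FAM203A (2.03 to -0.24), SESN1 (0.61 to -0.16) and SRC (0.99 to -0.11) with the mimic and PRKRA (2.53 to -0.27) with the sponge, since the sum counts their other transcripts. Scaling by the upper quartile shifted the median of all genes in the sponge comparison by -0.12, and the median of ratios by -0.078. Depth limits the low genes: IFI6, at 0.22 RPKM with the mimic, has a counting interval of -8.21 to -4.35. With 1 library per group no alternative replaces a replicate.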

Other observations

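Set against the MCF-7 control, the MDA-MB-231 control and not the sponge library stood further apart for several gene groups. Cholesterol synthesis genes had a median log2 ratio of -1.55 in the MDA-MB-231 control and -0.10 in the sponge library, unfolded protein and stress response genes 1.52 and -0.60, NF-kB and inflammatory genes 2.54 and 1.45, and glutamine metabolism genes 0.43 and 0.03. Cell cycle genes stood on either side, at -0.88 in the MDA-MB-231 control and 0.85 in the sponge library. Interferon genes, ribosomal proteins and microtubule genes showed the reverse, with the sponge library further from the MCF-7 control: 0.92 against 0.13 for 30 interferon genes (0.55 in the MDA-MB-231 control over the 29 genes that pass the filter between the controls), -0.35 against -0.02 for ribosomal proteins and 0.79 against 0.12 for microtubule genes. These medians describe 3 libraries and were chosen after the data were seen.

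MUC5B, a secreted mucin, was higher with the mimic (8.58 against 2.75 RPKM) and lower with the sponge (0.30 against 6.04 RPKM), and B3GNT3, a glycosyltransferase that acts on mucin-type glycans, followed it at 6.96 against 2.18 and 0.88 against 4.43 RPKM. TGM2 was higher in both manipulated libraries, at 11.03 against 1.88 RPKM in MCF-7 and 91.3 against 19.7 RPKM in MDA-MB-231. Genes whose best miR-23 match is a 6mer lay at the 99.7 percentile of matched lists in the mimic library (1229 genes, median 0.022). Those lists hold 7mer and 8mer genes, which the 6mer class leaves out by definition, so this percentile does not show that the class was raised. From genes without a 6mer the class differed by -0.0075. For miR-26 the 6mer class lay at the 98.2 percentile.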
